A study of Apis mellifera with 24 samples.

How the data were processed

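PolyA RNA from the brains of 24 individual honey bee workers was sequenced by the authors as paired ends over 2 lanes. Status, lineage, cross and block were taken from the deposited sample labels, which give 8 groups of 3 bees. The submitters' processing notes name HISAT2 and limma, without a version or a role. The counting tool, the genome build, the annotation and the rule that assigned reads to a parental allele are not given in the sources used here. The deposited expression table holds expected counts (estimated read counts, 87.3% of them exactly whole, with a tolerance of 0) for 15314 gene identifiers and 24 libraries, of which 2836 had no count in any library. Its values were not scaled to a common total. Per the file headers, the allele tables hold read counts per gene assigned to the drone (paternal) or the queen (maternal) allele of each bee. They cover 3532 genes in reproductive bees and 3572 in sterile bees after identical repeated entries (3 and 1) were reduced to 1 each. All columns of values per bee were used.

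Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr, which left 9316, and edgeR 4.0.16 in R 4.3.3 was fitted with TMM factors and quasi-likelihood tests. The pooled status comparison had lineage and status as terms. Contrasts within lineages, between the cross directions in each block and for the difference in status effect between directions came from a model with 1 mean per group. A gene counted for the cross direction when it passed in both blocks with the same sign. The threshold was a Benjamini-Hochberg adjusted p of 0.05, and tests were two-sided except the shuffles of sides, which were one-sided. Adjusted p values are from edgeR unless DESeq2 1.42.0 or limma 3.58.1 is named.

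Allele reads were tested in edgeR with a maternal and a paternal column per bee, the same library size for both, bee as a block, and terms for parent and for African against European allele. Genes needed at least 20 allele reads in every lineage of that status. The difference in parental ratio between statuses was tested over both tables with status terms for parent and allele. Log ratios for limma used a prior count of 0.5. The paternal share of the called genes was given an exact binomial interval at the 95% level. The median paternal share per bee was compared between statuses by exact permutation within lineages, and between cross directions by exact permutation of 6 bees against 6. Correlations over the 24 libraries used deviations from lineage means and 1e+05 permutations within lineages.

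The comparisons, the alternatives planned, the gene lists and the rule for named genes were set before the data were examined. The rule took, per comparison, the called genes with the largest changes in each direction and those with the smallest p, and limited genes without a name to 2 identifiers per direction. For allele reads a named gene needed at least 100 reads. Where the gene with the largest change also had the smallest p, only that gene is given for its side. The identifiers are paired with no name in the tables, and 0 of the 15314 occur in the reference table used, so the 22 gene lists could not be tested.

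The alternatives planned were other size factors, other count filters (none, or 10 counts in 12 bees), DESeq2, limma (voom with lineage as a random effect for status, log ratios per bee for allele reads), other minimums of allele reads (10 and 50), a minimum bias of 60%, exact tests on summed reads, each block alone, each lineage left out for status, and each bee left out. For status, a fit without a lineage term, 1 mean per group, the lineages of each cross direction alone and a minimum of 1.5-fold were planned too. For the tests on summed reads, Fisher's exact test applies to the comparison of statuses, and the exact binomial test was used within a status, where a second column is lacking. After the data were seen, limma voom with lineage as a fixed term and the share of the 10 most abundant genes as a covariate were added for status. For allele reads, limma with lineage as a random effect and on lineage means, each lineage left out, and whole lineages with parental columns exchanged were added. The exchange of the status of L888, the share of counts in the 10 most abundant genes with all its settings, the shuffles of sides among genes biased in all 4 lineages, the thinning of neighbouring genes and the other pairings of whole lineages were also added then. The settings for normalized values and for single variants did not apply to these tables.

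The fits were tested on simulated data with the same numbers of bees and genes. Each gene was drawn on its own, so differences that many genes of a bee share were absent. edgeR recovered 47.8%, 86.6% and 97.0% of genes with differences of 1.5, 2 and 4-fold, with 9 false calls. Parental shares of 55%, 60% and 75% were recovered in 17.9%, 50.7% and 89.4% of genes in reproductive bees, with 7 false calls, and in 22.4%, 43.3% and 89.4% in sterile bees, with 5 false calls. The simulated allele reads of each bee were drawn on their own, so parental shares that sisters of a lineage have in common were absent. These false calls therefore do not give the error rate of the parental calls in the real bees. Total counts per bee ran from 5.19 to 16.7 M and allele reads from 3.27 to 9.33 M. Reads are not independent molecules, so the counting intervals cover counting error only. Raw reads were not used here.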

Results

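Brains of 24 individual honey bee workers were profiled by polyA RNA sequencing. The workers came from reciprocal crosses of Africanized (Afr) and European (Eur) bees and were kept for about 18 days in colonies without a queen, where workers can activate their ovaries and lay eggs. The crosses are written with the mother first. Lineages L875 and L882 were Eur x Afr, and lineages L888 and L894 were Afr x Eur. Block A held L875 and L888, and block B held L882 and L894. Each lineage gave 3 reproductive and 3 sterile bees, so that 12 bees stood on each side. Because each cross was made in both directions, the maternal and paternal copies of a gene can be followed apart from the African or European origin of the copy. The series title names the kinship theory of conflict within genomes as the subject, which concerns differences in the expression of maternal and paternal gene copies in relation to worker reproduction.

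Total expected counts per bee, in M (mega) counts, ran from 5.19 to 16.7 M, with a mean of 10.9 M ± 2.60 (SD, n = 24). In L875 they ran from 7.97 to 11.3 M in reproductive bees and from 8.39 to 13.2 M in sterile bees. In L882 the ranges were 5.19 to 11.1 M and 10.9 to 14.4 M, in the same order. In L888 they were 8.61 to 11.03 M and 8.88 to 10.2 M, and in L894 they were 10.7 to 16.7 M and 13.5 to 14.4 M. Reproductive bees had 10.2 M ± 2.80 (SD, n = 12) and sterile bees 11.6 M ± 2.28 (SD, n = 12). This difference did not pass an exact two-sided permutation test of status within lineages (p = 0.121; adjusted p = 0.202 over 5 measures per library). Reads assigned to a parental allele ran from 3.27 to 9.33 M per bee. The tables pair no gene identifier with a gene name, so that genes are given by identifier only, and none of the 22 gene lists chosen before the data were examined had a measured member.

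The first comparison asked which genes differ between the brains of reproductive and sterile workers. No gene of the 9316 tested differed in level between the 12 reproductive and the 12 sterile brains once lineage was taken into account. The gene with the smallest p was GB51356, chosen after its values were seen, at 15.6 ± 12.6 CPM (counts scaled to a common library size) in reproductive brains and 52.0 ± 31.3 in sterile brains (SD, n = 12 each). Its log2 difference was -1.96 (SE 0.39), it was lower in reproductive bees in 4 of 4 lineages, and its adjusted p was 0.430 in edgeR and 0.00659 in DESeq2. GB47563, chosen in the same way, had 90.7 ± 69.6 CPM in reproductive brains and 33.02 ± 45.01 in sterile brains (SD, n = 12 each), a log2 difference of 1.87 (SE 0.45) with an adjusted p of 0.9998. It was higher in reproductive bees in 4 of 4 lineages and had an adjusted p of 0.0203 with lineage L888 left out and of 0.0162 in the Eur x Afr lineages alone.

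In edgeR, 216 genes had an unadjusted p under 0.05 for status and 0 passed the adjusted threshold. With lineage and status as terms, DESeq2 called 1 gene, GB51356, and limma voom called 0 genes. With 1 mean per group, DESeq2 called GB45796, GB49508 and GB51356 for status (adjusted p = 6.38e-04, 0.0219 and 2.26e-04). Without the bee L875 Sterile 3, edgeR called 1 gene. Block A alone and block B alone each gave 0 genes in edgeR, with 118 and 426 genes at an unadjusted p under 0.05. In simulated data of the same size, edgeR recovered 47.8% of genes with a 1.5-fold difference, 86.6% with a 2-fold difference and 97.0% with a 4-fold difference. The simulation changed 67, 67 and 66 genes and drew each gene on its own, without differences that many genes of a bee share. In the real bees GB51356, with a log2 difference of -1.96, had an adjusted p of 0.430 in edgeR. The simulated rates therefore do not rule out status differences of 2 to 4-fold.

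Within single lineages, reproductive and sterile brains also showed 0 called genes in edgeR in each of the 4 lineages. The numbers of genes at an unadjusted p under 0.05 were 140 in L875, 207 in L888, 357 in L882 and 521 in L894. DESeq2 called 2 genes in L875, 0 in L888, 1 in L882 and 5 in L894. In L894, edgeR called 1 gene when L888 Sterile 2 was left out and 1 when L894 Sterile 3 was left out. The log2 differences of the 4 lineages were weakly related to each other across the 9316 genes, with Pearson's r from -0.11 to 0.19. Genes are not independent replicates, so no p is given for these values. The difference in the status effect between cross directions was tested directly, and edgeR called 0 genes, with 583 at an unadjusted p under 0.05. DESeq2 also called 0 genes, with 625 at an unadjusted p under 0.05.

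The next comparison asked whether the maternal or the paternal copy of a gene was expressed more. In reproductive brains, 348 of 3475 genes differed between the parental copies, and 336 of these were higher from the father. The other 12 were higher from the mother. In sterile brains, 326 of 3480 genes differed, 316 of them higher from the father and 10 higher from the mother. The father's copy was thus the higher one in 96.6% of the called genes in reproductive bees (exact binomial 95% interval 94.1 to 98.2) and in 96.9% in sterile bees (94.4 to 98.5). These intervals treat genes as independent, which they are not, and cover counting error only. The fits had no term for lineage, so sisters with the same parents counted as separate replicates of a parental difference. The counts, and the adjusted p values of single genes below, therefore do not cover differences between families. With lineage as a random effect, limma called 79 genes in reproductive and 96 in sterile bees, and on lineage means 0 in both. How reads that match both parental alleles were assigned is not given in the sources used here, and any counted for both would draw the printed shares and ratios towards balance.

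Among genes higher from the father in reproductive brains, GB46378 had the largest difference, with a log2 ratio of paternal to maternal reads of 4.11 (SE 0.67, adjusted p = 0.00533). Its paternal share was 98.2% ± 3.1 in L875, 99.4% ± 1.1 in L882 and 93.7% ± 4.0 in L888, but 50.95% ± 0.41 in L894 (SD, n = 3 each). GB41608 had the smallest p on the paternal side, with a log2 ratio of 2.34 (SE 0.13, adjusted p = 6.29e-06). Its share was 94.0% ± 2.1 in L888 and 96.6% ± 0.48 in L894, and 53.6% ± 1.7 in L875 and 54.8% ± 6.8 in L882. GB49183 had the largest difference on the maternal side, with a log2 ratio of -6.41 (SE 0.50, adjusted p = 4.49e-05). The father's copy of this gene gave 4.12% ± 4.4 of the reads in L875 and 0.538% to 1.13% in the other lineages. GB45619 had the smallest p on the maternal side, at -2.27 (SE 0.15, adjusted p = 1.47e-05), with paternal shares of 7.10% in L888, 7.52% in L894, 30.4% in L875 and 40.96% in L882.

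In sterile brains, GB51729 had the largest paternal difference, with a log2 ratio of 4.67 (SE 0.67, adjusted p = 0.00415), and its paternal share lay between 81.8% in L894 and 99.5% in L882. GB44091 had the smallest p on the paternal side, with a log2 ratio of 0.62 (SE 0.04, adjusted p = 2.20e-05) and shares of 56.0% in L875, 56.7% in L882, 63.5% in L894 and 65.7% in L888. GB49639 had the largest maternal difference, at -5.32 (SE 1.16, adjusted p = 0.0188), and GB49655 had a log2 ratio of -5.01 (SE 1.04, adjusted p = 0.0165). The paternal share of GB49639 was 0.431% in L875, 1.91% in L882 and 2.44% in L894. In L888 it was 49.8% ± 47.5 (SD, n = 3), so that the sterile sisters of that lineage differed widely. GB49655 had 48.5% ± 45.4 in L888 (SD, n = 3), and 0.410% in L875, 3.51% in L882 and 3.34% in L894.

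The number of genes with a parental difference depended on how the 4 families were treated. With lineage as a random effect in limma, 79 genes were called in reproductive bees, 70 paternal and 9 maternal, and 96 in sterile bees, 95 paternal and 1 maternal. With lineage means as the unit, 0 genes were called by limma in either status, where limma on single bees called 418 and 354. With a paternal or maternal share of at least 60% required in both cross directions, 63 and 53 genes were called. Block A alone gave 253 genes in reproductive and 215 in sterile bees, and block B alone 331 and 273. With L882 left out, 115 and 78 genes were called, and with L875 left out 145 in sterile bees. Leaving out single bees gave 212 and 222 genes in reproductive bees, without L882 Reproductive 2 and 3. In sterile bees it gave 210, 212 and 198 without L882 Sterile 1, 2 and 3, and 217 without L875 Sterile 1.

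Lineage by lineage, many more genes leaned to the father than to the mother. Whatever the other lineages showed, in reproductive bees 390 genes of L875, 584 of L882, 769 of L888 and 812 of L894 had over 60% of their reads from the father. Between 125 and 168 genes per lineage had over 60% from the mother. Genes that leaned the same way in all 4 families were few, 27 in reproductive bees (18 paternal, 9 maternal) and 28 in sterile bees (23 paternal, 5 maternal). When genes were shuffled within lineages 1000 times, the highest counts were 10 and 11. A stricter test, chosen after the data were seen, kept the 90 and 95 genes that leaned beyond 60% to either side in every lineage and shuffled only their sides. It gave means of 13.7 and 14.3 genes (one-sided permutation p = 3.00e-04 in reproductive bees, and 1e-04 in sterile bees, the smallest possible). Genes that followed the African or European copy in all 4 lineages numbered 16 in reproductive bees and 16 in sterile bees. Genes that split by block numbered 8 and 7, and those with the remaining split numbered 5 and 5, where the shuffles reached at most 4. Across genes, the paternal shares of reproductive and sterile sisters of 1 lineage were related with r from 0.63 to 0.69, and those of different lineages with r from -0.03 to 0.17. Genes are not independent replicates.

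**Figure D1:**
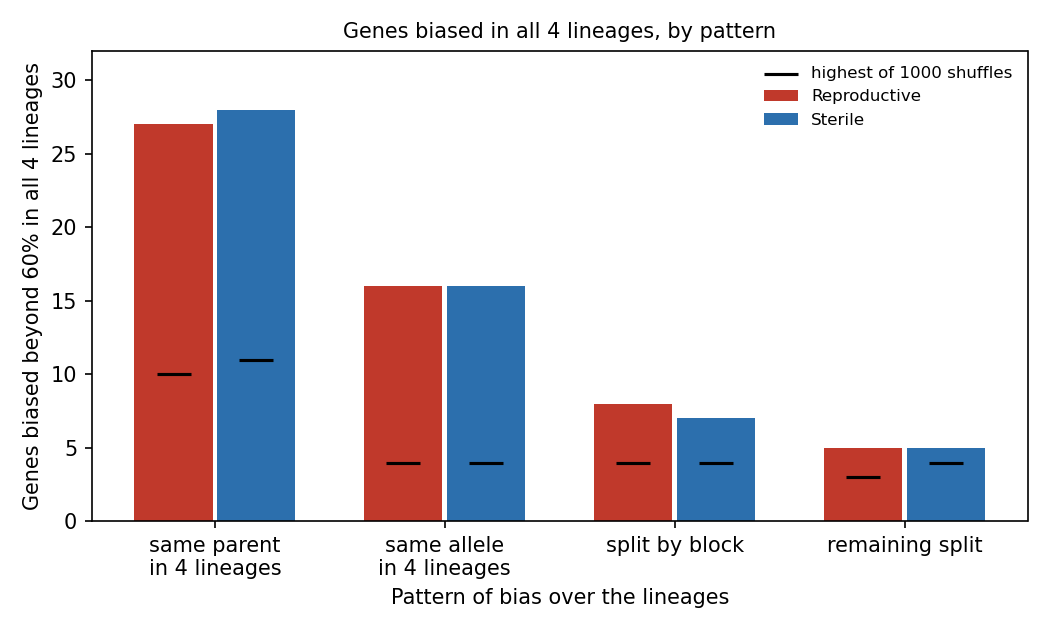
Number of genes with over 60% of reads from 1 side in all 4 lineages, by pattern (horizontal axis) and status (bar colour). Black marks give the highest count in 1000 shuffles of genes within lineages. The parental pattern holds 27 and 28 genes, against at most 10 and 11 in the shuffles. The other patterns also exceed their highest shuffles.

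The same fits asked whether the African or the European copy of a gene was expressed more. In reproductive brains 102 genes differed, 86 of them higher from the European copy and 16 from the African copy. In sterile brains 79 genes differed, 74 higher from the European copy and 5 from the African copy. Sisters again counted as separate replicates, so these counts and the adjusted p values below do not cover differences between families. With L875 left out, 64 genes were higher from the African copy and 56 from the European copy in reproductive bees, and 21 and 16 in sterile bees. In block B alone, which holds no L875, 62 genes were higher from the African and 137 from the European copy in reproductive bees, and 52 and 116 in sterile bees. Single bees also moved the counts, to 45, 61 and 62 genes without L882 Reproductive 1, L882 Reproductive 2 and L894 Reproductive 3, and to 49 and 50 without L875 Sterile 3 and L882 Sterile 3. GB48687 was higher from the African copy in both statuses, with log2 ratios of African to European reads of 3.68 (SE 0.24, adjusted p = 1.52e-05) in reproductive bees and 3.52 (SE 0.34, adjusted p = 2.60e-04) in sterile bees. Its paternal share in reproductive bees was 95.3% in L875 and 89.3% in L882, whose fathers were African, and 6.97% in L888 and 6.53% in L894, whose mothers were. GB48215 was higher from the European copy in reproductive bees, at -3.13 (SE 0.33, adjusted p = 5.47e-04). GB41608, which also had more paternal reads, had a log2 ratio of -2.10 for the African copy (SE 0.13, adjusted p = 1.52e-05). In sterile bees GB47520 had -3.51 (SE 0.29, adjusted p = 1.28e-04) and GB50417 had -1.42 (SE 0.09, adjusted p = 3.66e-05). With lineage as a random effect, limma called 23 genes in reproductive and 25 in sterile bees, and with lineage means as the unit it called 0 and 0. Block A alone gave 211 and 185 genes, and block B alone 199 and 168, in reproductive and sterile bees.

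The kinship question then turned on whether parental expression differs between reproductive and sterile workers. No gene of 3414 showed a difference in its parental ratio between the statuses, by edgeR (100 genes at an unadjusted p under 0.05) or by limma (113 at an unadjusted p under 0.05). The simulation did not cover this comparison. Within a status, simulated shares of 60% were recovered in 50.7% of genes in reproductive and 43.3% in sterile bees. The count of 0 thus does not show that the ratios are equal. Across the 3414 genes, the log2 ratios of the statuses were related with r = 0.77, and genes are not independent replicates. Of the genes measured in both statuses, 335 were called paternal in reproductive bees and 313 in sterile bees, and 141 were shared, where 30.7 would be shared if the statuses were independent. They were not, since reproductive and sterile sisters of a lineage had the same parents, so no p is given. On the maternal side 12 and 10 genes were called and 6 were shared. The count for the difference was not 0 in every part of the data. Block A alone gave 2 genes and block B alone gave 29. Leaving out L888 gave 27 genes, leaving out L894 gave 8, and leaving out L875 gave 1. In L888 the header letters A and I stand with the statuses the other way round than in the other lineages. With the status of L888 exchanged, edgeR called 0 genes, with 84 at an unadjusted p under 0.05. Fisher's exact test on reads summed over bees, which leaves out the spread between bees, gave 266. Because 0 genes differed by status in total expression, at an adjusted p of 0.05 or of 0.1, no overlap with the genes that had a parental difference could be tested.

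**Figure D2:**
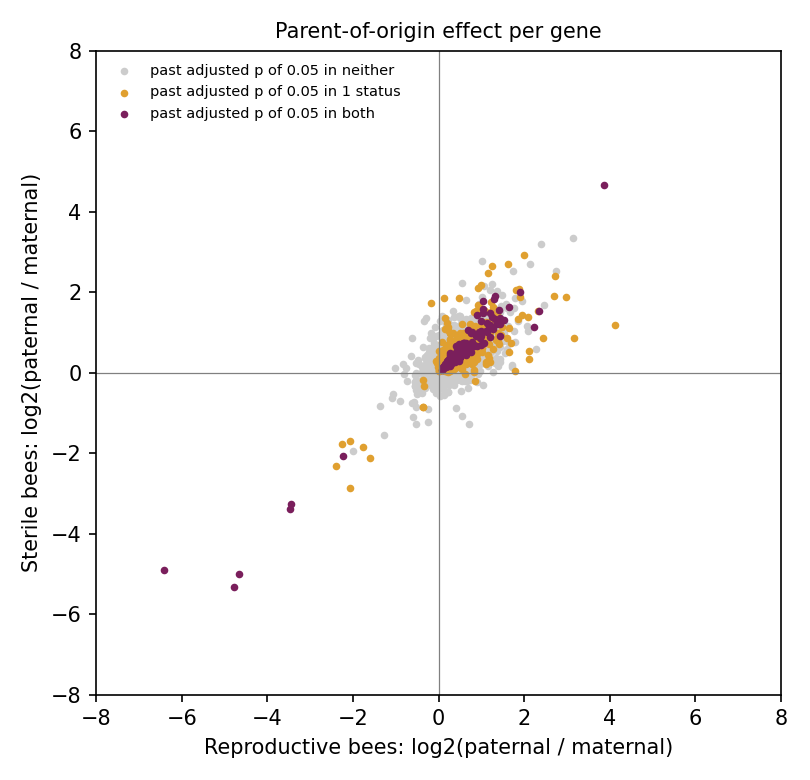
Log2 ratio of paternal to maternal reads for 3414 genes in reproductive bees (horizontal axis) and sterile bees (vertical axis). Each point is a gene, coloured by whether it passed the adjusted threshold in neither status, in 1 or in both, and the ratios are related across genes with r = 0.77.

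Each bee also showed a small overall lean to its father. The median paternal share over genes was above 50% in 24 of 24 bees, with a mean of 50.8% ± 0.55 in reproductive bees and 51.04% ± 1.0 in sterile bees (SD, n = 12 each). Reproductive and sterile bees did not differ in an exact two-sided permutation test within lineages (difference -0.188 points, p = 0.586; adjusted p = 0.586 over 5 measures). The difference was -0.440 points in block A (exact p = 0.365) and 0.0643 points in block B (exact p = 0.530), and without the bee L888 Sterile 2 it was 0.00876 points. Of all allele reads, 52.9% ± 1.1 were paternal in reproductive bees and 52.3% ± 1.7 in sterile bees (SD, n = 12 each; exact permutation p = 0.236). In block A this difference was -0.487 points (exact p = 0.685) and in block B 1.56 points (exact p = 0.01, adjusted p = 0.0250).

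The lean was larger where the father was European. Among reproductive bees, the median paternal share was 51.3% ± 0.24 in Afr x Eur and 50.4% ± 0.24 in Eur x Afr (SD, n = 6 each; difference 0.969 points, exact two-sided permutation p = 0.00216). Among sterile bees it was 51.8% ± 0.93 and 50.2% ± 0.12 (SD, n = 6 each; difference 1.58 points, exact two-sided permutation p = 0.00216). This p is the smallest that 924 labellings allow. Within block A the differences were 1.05 points in reproductive and 1.97 points in sterile bees, and within block B 0.885 and 1.19 points. With 3 bees against 3, an exact test cannot go below p = 0.1, and each of these 4 differences had that p. Each direction held only 2 lineages, so that bees are not replicates of the direction.

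**Figure D3:**
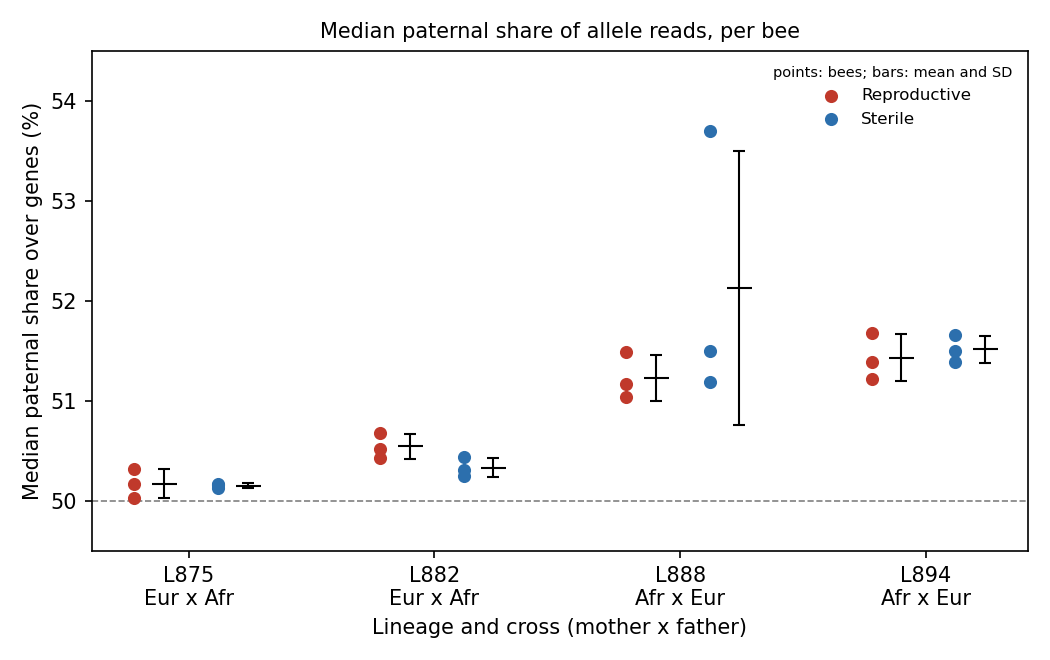
Median paternal share of allele reads over genes (%, vertical axis) for each bee, by lineage and status. Points are bees and bars are the mean and SD of 3 bees, and the dashed line marks 50%. All 24 bees lie above 50%, and Afr x Eur bees lie higher than Eur x Afr bees.

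Gene levels were then compared between the directions of the cross, separately in each block. GB51422 was the single gene called in both blocks, and it was higher in Afr x Eur bees. It had 38.9 ± 3.4 CPM in L888 and 20.4 ± 4.4 in L875, a log2 difference of 0.93 (adjusted p = 0.00973). In block B it had 33.6 ± 6.8 in L894 and 19.3 ± 3.0 in L882 (SD, n = 6 each), a log2 difference of 0.80 (adjusted p = 0.0320). Block A gave 14 genes, 7 higher in L888 and 7 lower, and block B gave 11 genes, 6 higher in L894 and 5 lower. The log2 differences of the blocks were related across the 9316 genes with r = -0.25, and genes are not independent replicates. DESeq2 called 2 genes in both blocks, GB51422 among them. When lineages of the same direction were compared instead, an arrangement chosen after the data were seen, 22 genes were shared by L882 against L875 and L894 against L888. The remaining pairing of lineages shared 12 genes in the same direction. Both arrangements set block B against block A in each pair, so a difference between blocks would give such genes too. The edgeR call of GB51422 was lost in block B with upper-quartile factors, where 0 genes remained. It was also lost when any of 11 bees was left out, which were the 3 reproductive bees of L882, the 3 reproductive bees of L894, L882 Sterile 1 and 2, L894 Sterile 1 and 3, and L888 Sterile 3. Without each of these 11 bees, the log2 difference in block B stayed between 0.76 and 0.85, with adjusted p from 0.0525 to 0.136. With upper-quartile factors it was 0.78 (adjusted p = 0.0631).

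How much of the RNA came from a few abundant genes was also compared, a measure chosen after the data were seen. The 10 genes with the highest mean share of counts over the 24 libraries held 27.2% ± 18.1 of the counts in reproductive brains and 44.7% ± 17.4 in sterile brains (SD, n = 12 each). The difference was -17.6 points (exact two-sided permutation p = 0.0123 within lineages), and it did not pass the threshold after adjustment over the 5 measures per library (adjusted p = 0.0615). The mean was lower in reproductive bees in 4 of 4 lineages, by -10.7 points in L875, -11.1 in L888, -26.1 in L882 and -22.3 in L894, and exact tests with 3 bees against 3 cannot go below p = 0.1. In block A the difference was -10.9 points (exact p = 0.305) and in block B -24.2 points (exact p = 0.0150). Of these 10 genes, 9 had a log2 difference below 0, with a median of -1.02 and a range of -2.33 to 0.05. Of the 9, GB43247 had -0.03 (SE 0.63), with -1.49 in L875, -1.75 in L888, 1.40 in L882 and 1.74 in L894. GB55204, GB55205, GB55206, GB55212 and GB55213 have neighbouring identifiers, so the 10 genes may not vary separately, which was not tested. None of the 10 passed the adjusted threshold in edgeR, and a two-sided fry test of the set gave p = 0.0530 (n = 12 bees per status). DESeq2 with 1 mean per group called GB45796, which is among the 10, for status (log2 difference -3.13, adjusted p = 6.38e-04). The same fit called it within L894 (-8.61, adjusted p = 3.65e-09). With lineage and status as terms, DESeq2 did not call it.

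**Figure D4:**
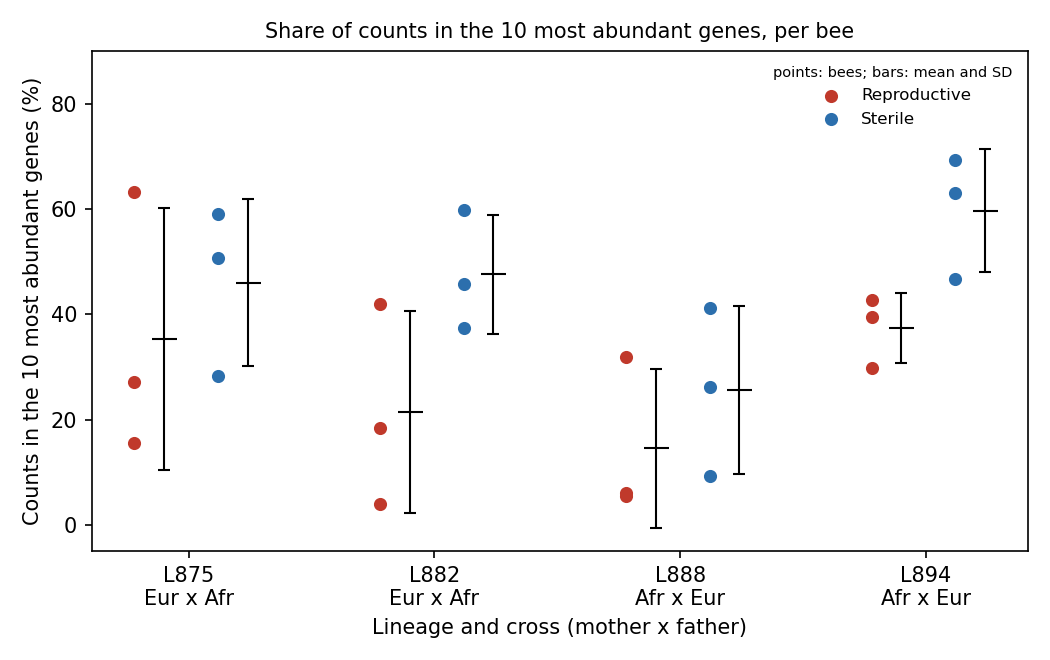
Share of the counts held by the 10 most abundant genes (%, vertical axis) for each bee, by lineage and status. Points are bees and bars are the mean and SD of 3 bees. The mean is lower in reproductive than in sterile bees in 4 of 4 lineages.

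The share of the abundant genes followed the size of the library. Within lineages, it rose with the log2 total count (Pearson's r = 0.753, permutation p = 7.00e-05, adjusted p = 1.40e-04; Spearman's rho = 0.754, permutation p = 1.80e-04, adjusted p = 3.60e-04; n = 24, 2 relations). Without the 2 libraries farthest from the median of total count, r was 0.665. It fell as the log2 count outside the 10 genes rose (r = -0.596, permutation p = 0.00272, adjusted p = 0.00272; rho = -0.672, permutation p = 8.80e-04, adjusted p = 8.80e-04), and without the 2 farthest libraries r was -0.574. The share is computed from these same counts, so part of each correlation is built in. With the total count removed by regression, the status difference was -8.93 points (exact permutation p = 0.0564), lower in 3 of 4 lineages. Of 9306 other genes, 1659 followed the share in edgeR, 724 upward and 935 downward.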

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

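The test of a mapping preference and the thinning of neighbouring genes were chosen after the result was seen, and the other tests on sisters were set before theirs. The median paternal share over genes differed between the cross directions, by 0.969 points in reproductive bees and 1.58 points in sterile bees, higher in Afr x Eur in both (exact two-sided permutation p = 0.00216 each, the smallest possible). It stood out because the parental lean differed between the directions in a direct test. Each direction held 2 lineages, so that direction and lineage are confounded.

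The lean to the father in all 24 bees is the wider pattern. A preference of the mapping for European alleles as the whole cause would put Eur x Afr bees below 50%, and 12 of 12 lay above, though such a preference may add to the difference between directions. Maternal copies that segregate among sisters, so that some sisters lack distinguishable maternal reads, would leave little paternal excess where the 6 sisters agree. There, 74.5% of 137 biased gene and lineage pairs were paternal (exact 95% interval 66.3 to 81.5), with 9 paternal and 9 maternal in L875, and the interval was 66.3 to 82.5 over the 120 pairs left when genes of a lineage lay more than 10 identifiers apart. Single sisters that stray to either parent alike would give about 50%, and 80.4% of 2965 such pairs were paternal (78.9 to 81.8). Over 1621 pairs so thinned the interval was 77.7 to 81.7. Segregating maternal copies would also give more paternal pairs there. Equal segregation would leave about 18.3 paternal pairs among agreeing sisters, where 102 were seen. Agreeing sisters held only these 102 of the 1559 paternally biased pairs, and sisters that varied by over 20 points held 1134. For most of the excess, segregating maternal copies thus remain open. A parental effect on expression and parent-dependent mapping or read assignment remain open as well.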

How the results depend on the processing

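Settings chosen after the data were seen were lineage left out, as a random effect or as the unit for allele reads, lineage as a fixed term in limma voom and the abundant share as a covariate for status, exchanged L888 status and all settings of the abundant genes. The cause of a change was not tested unless given. Over all results, 851 alternatives kept the value and 139 did not: a tested value kept its direction and side of the threshold, a count stayed within 1.5 times, a percent stayed inside its 95% interval. For the genes named, 437 of 479 alternatives kept direction and call, 39 lost a call, 3 gained one and 0 turned direction. With lineage means as the unit no named allele gene was called. No paired analysis was possible because the labels give no numbers that pair bees of different status.

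Genes by status numbered 0, and 1 with DESeq2 (lineage and status as terms), with L888 left out and in Eur x Afr alone. Within lineages DESeq2 gave 2 (L875), 1 (L882) and 5 (L894) for 0. The gene in both blocks was lost with upper-quartile factors (0), and DESeq2 gave 2. The adjusted p of GB51356 ran from 0.00659 to 1 over its alternatives. DESeq2 with 1 mean per group, outside these alternatives, gave 2.26e-04.

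Parental genes numbered 348 (reproductive) and 326 (sterile). The 60% minimum gave 63 and 53, exact tests on summed reads 872 and 881, and lineage as a random effect 79 and 96. Lineage means gave 0 and 0, with fewer units. L882 left out gave 115 and 78. In sterile bees block A alone gave 215 and L875 left out 145. Genes by African or European copy numbered 102 and 79. The 60% minimum gave 23 and 19, exact tests 336 and 334, block A alone 211 and 185, block B alone 199 and 168, L888 left out 233 and 206, L894 left out 255 and 255, the random effect 23 and 25, and lineage means 0 and 0. In sterile bees L875 left out gave 37 and L882 left out 42. The European excess turned with L875 left out, to 64 African and 56 European genes in reproductive and 21 and 16 in sterile bees. The difference in parental ratio by status gave 0 genes, exact tests 266, block A alone 2, block B alone 29, L875 left out 1, L888 left out 27 and L894 left out 8.

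The paternal percent of called genes was 96.6 in reproductive bees. It was 84.1 with the 60% minimum, 88.5 in block A, 91.2 in block B, 92.0, 86.96 and 93.6 with L888, L882 and L894 left out, and 88.6 with the random effect. In sterile bees it was 96.9, and in the same order 86.8, 94.4, 91.6, then 93.3 and 92.3 with L888 and L882 left out, 100 with L875 left out and 98.96 with the random effect.

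The share of the 10 most abundant genes (-17.6 points) no longer passed the unadjusted threshold for the most abundant gene alone (-7.06), in block A (-10.9), with L882 or L894 left out (-14.7, -16.0), with L888 exchanged (-12.0) or with the total count removed (-8.93). The status difference in median paternal share (-0.188 points) turned to 0.0643 in block B and 0.00876 without L888 Sterile 2. The difference between directions was 1.05 and 0.885 (reproductive, blocks A and B) and 1.97 and 1.19 (sterile), where 3 bees against 3 cannot pass.

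With each bee left out, status gave 0 to 1 genes (1 without L875 Sterile 3), L875, L888 and L882 0 to 0, L894 0 to 1 (1 without L888 Sterile 2 or L894 Sterile 3), both blocks 0 to 1 (0 without 11 bees: L882 Reproductive 1 to 3, L894 Reproductive 1 to 3, L882 Sterile 1 and 2, L894 Sterile 1 and 3, L888 Sterile 3) and the differences in status effect and in parental ratio 0 to 0. Parental genes ran from 212 to 297 in reproductive bees (212 and 222 without L882 Reproductive 2 and 3) and from 198 to 299 in sterile bees (217 without L875 Sterile 1; 210, 212 and 198 without L882 Sterile 1, 2 and 3). Genes by copy ran from 45 to 110 (45 and 61 without L882 Reproductive 1 and 2, 62 without L894 Reproductive 3) and from 49 to 92 (49 without L875 Sterile 3, 50 without L882 Sterile 3). Percent paternal ran from 93.9 to 96.5 and from 94.3 to 97.9, lowest without L888 Reproductive 2 and L888 Sterile 2. The abundant share ran from -21.0 to -15.1, the status difference in paternal share from -0.305 to 0.00876, and that between directions from 0.899 to 1.03 and from 1.20 to 1.71. Small biases were often missed: simulated shares of 55% were recovered in 17.9% and 22.4% of genes, and how much of this is due to depth was not tested.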

Other observations

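The tests of identifier distance, of shuffled sides, of whole lineages for the cross direction, of the assignments that called genes, of exchanged labels in L888 and of single bees against their sisters, and the share of counts in abundant genes itself, were chosen after the values were seen. Among genes higher from the European copy, 85 in reproductive and 72 in sterile bees were measured in both statuses, and 30 were shared, where 1.79 would be shared if the statuses, which have the same parents, were independent. Of the genes higher from the African copy, 16 and 5 were called and 3 were shared. Genes are not independent replicates.

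Genes with over 60% of reads from 1 parent in all 4 lineages numbered 27 in reproductive and 28 in sterile bees. A parental bias shared by families predicts more such genes than any of 1000 shuffles of genes within lineages, and the highest shuffles had 10 and 11. The block pattern (8 and 7 genes) and the remaining pattern (5 and 5) also exceeded their shuffles, which reached at most 4. No parental effect describes these patterns, so exceeding the shuffles does not single out a parental bias. Family haplotypes alone cannot be told apart from it by the patterns that no cross describes (at most 8 and 7 genes), because the lean to the father gives the parental pattern more genes by chance, 3.38 against 0.413 in reproductive bees. Haplotypes whose sides are independent between families would give 13.7 and 14.3 genes when each family keeps its lean, fewer than the 27 and 28 (one-sided permutation p = 3.00e-04 and 1e-04), and with genes more than 10 identifiers apart 20 and 26 stood against 12.5 and 14.5 (p = 0.00850 and 1e-04), though in reproductive bees 15 paternal genes stood against 11.3 (p = 0.0798) and 5 maternal against 1.26 (p = 0.00390). Haplotypes may thus account for part of the genes, and for the rest a shared parental effect, haplotypes shared between families and parent-dependent mapping remain open.

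The smaller share of counts in the 10 most abundant genes of reproductive brains followed library size within lineages (r = 0.753), as a difference in library size predicts. The total count includes these genes, and the count outside them fell with the share (r = -0.596). The share is computed from these same counts, so part of each correlation is built in. The correlations therefore cannot tell whether the share follows library size or library size follows the abundant genes. With the total count removed, -8.93 of the -17.6 points were left. Exchanged status labels in L888 cannot be told apart from true ones, because L888 showed -11.1 points, the sign of the other lineages, with only 3 bees per status. A difference in the brains or in dissection stays open and untested.

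Other assignments of the bees were compared with the real ones, 100 for each result, the real one included. For status, for the difference in status effect between directions and for the difference in parental ratio between statuses, the real count was 0, which all 100 assignments must reach, so that they say nothing about chance. For status, 3 of the 99 others called any gene, at most 244. For the status effect between directions 5 did, at most 1040, and for the parental ratio 10 did, at most 4. By the difference in the share of the 10 most abundant genes, the assignment with 244 genes ranked 9 of 99 and that with 1040 ranked 10 of 99, and what sets these assignments apart stays open. For the gene called in both blocks, chance assignment of single bees was excluded, 1 against 0 (1 of 100 assignments gave as many). Bees of a lineage are sisters, so the 5 other arrangements of the 4 lineages were counted too. Differences between lineages whatever their cross direction predict as many genes in another arrangement, and the highest counts were 22 and 12. Both arrangements set a lineage of block B against a lineage of block A in each pair. A difference between blocks would give such genes too, so these counts cannot weigh lineage differences against the cross direction. The other arrangements gave 0 to 1 genes. Chance exchange of the parental columns of single bees was excluded for the parental counts, 348 against 3 and 326 against 2 (1 of 100 each). Chance assignment of single bees to a cross direction was excluded for the allele counts, 102 against 2 and 79 against 1 (1 of 100 each). Both the exchange and the assignment break up sisters with the same parents, which lowers the counts under differences between families too. Only chance among single bees was thus excluded, and differences between families were not. Within lineages the 10 splits of 6 bees are too few for this test: the real count was 0 in each lineage, and the highest other was 129 in L875 and 0 in L888, L882 and L894.

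Sisters share a father and a mother, so whole lineages were also exchanged. Of the 8 exchanges of parental columns, the real one gave the most genes, 348 against a highest other of 132 in reproductive bees and 326 against 101 in sterile bees. Lineage haplotypes and a parental effect cannot be told apart by this count, because 8 exchanges are too few. For the African and European copies, pairing the lineages by block gave 10 and 2 genes and the remaining pairing 23 and 15, where the cross directions gave 102 and 79. Such pairings are too few for lineage haplotypes and an effect of the African or European copy to be told apart by this count.

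Sisters deviated together at genes with neighbouring identifiers. The deviations of the paternal share from the lineage mean had a mean correlation of 0.274 for identifiers 1 apart, 0.181 for 2 apart, 0.0611 for 6 to 10 apart and 0.00608 for over 1000 apart. Chromosome stretches inherited whole by some sisters are a candidate explanation, if identifiers follow the genome, which was not tested here.

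The bee L888 Sterile 2 stood apart from its sisters. It read 2 of 5 genes mainly from the father that its 5 sisters read at least 80% from the mother, and no other bee did so for any gene. The mean correlation of paternal shares between L888 Sterile 2 and its sisters was 0.327, where the other 23 bees had 0.426 to 0.533 with theirs. L888 Sterile 2 also had the highest median paternal share, 53.7%. In the opposite sense, L894 Reproductive 3 read 1 of 13 genes mainly from the mother that its sisters read at least 80% from the father. All 24 allele libraries matched their own expression library better than any other.

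In gene and bee values with at least 100 allele reads, paternal and maternal counts were exactly equal in 7.20% in reproductive and 7.88% in sterile bees, where binomial sampling would give 1.998% and 2.07%. More than 3 SD of binomial sampling from balance were 33.1% and 32.6%, where sampling alone would give 0.265% in both. Reads counted for both parents would raise the share of equal counts and draw every paternal share and log ratio printed towards balance, and whether any were is not given in the sources used here and was not tested. In the headers of the allele tables, the letters A and I stand with the statuses of L888 the other way round than in the other 3 lineages. The groups used follow the sample labels.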
